A study of Homo sapiens with 9 samples.

How the data were processed

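RNA from MDA-MB-231 cells with the scramble, shco2 or shco4 hairpin, grown in DMEM with 10% fetal bovine serum, had been labelled as biotin-cRNA from 200 ng of total RNA and hybridized to 1 Affymetrix 3′ array per sample, 9 arrays in all. The deposited table holds 22277 probe sets with linear intensity values, 1 column per sample. The authors had scaled these intensities so that the mean without the lowest and highest 2% of probe sets was the same on every array, close to 500, as tested on the values; array medians differed by at most 0.0816 on the log2 scale. The software and the method of summary are not given in the sources used here. Groups and replicate numbers came from the sample labels, and 0 columns were left unmapped.

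Values under 16 were set to 16 and log2 was taken. The 62 control probe sets were left out, and the other 22215 were tested without a filter on dim probe sets. The annotation gave 1 symbol to 19064 of them, several to 1043 and none to 2108, with 11963 symbols in all. On all 9 arrays 2611 probe sets (11.8%) lay at the floor and could show no change. A difference from a group at the floor is a lower bound and is given as at least that many fold. For arrays, the number per group limits the precision.

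One linear model with a mean per group was fitted to all 9 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, and 4 contrasts were taken: shco2 and shco4 against scramble, the mean of both against scramble, and shco4 against shco2. Tests are two-sided, and p-values were adjusted by Benjamini-Hochberg over the 22215 probe sets of a contrast, with calls at an adjusted p under 0.05. The prior degrees of freedom were 0.53, a low value, with 2611 probe sets without spread in the fit. A probe set counts for both hairpins when both contrasts call it. Chance overlap with shared controls was simulated 100 times with groups without effect.

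Before the data were examined, 27 gene lists, the tests, the alternatives and the genes to name were fixed. The lists are BMP target genes; TGF-beta, activin and Nodal target genes; Wnt target genes; BMP, activin and Nodal ligands, receptors, antagonists and Smads; stem cell and pluripotency genes; YAP and TAZ target genes; mesenchymal, epithelial, lung metastasis, bone metastasis and dormancy-associated genes; G1/S and replication genes, G2/M and mitosis genes, interferon-stimulated genes, NF-kB and inflammatory cytokine genes, MHC class I and antigen presentation genes, p53 target genes, ATF4 and integrated stress response genes, endoplasmic reticulum chaperone and unfolded protein response genes, hypoxia and glycolysis genes, cholesterol synthesis genes, extracellular matrix and collagen genes, integrins and focal adhesion genes, matrix proteases and inhibitors, luminal breast line genes, fibroblast genes, and RNA interference genes. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 27 lists of a contrast, and again with an estimated correlation and with fry, using for each gene the probe set with the highest mean. Lists in the contrast of shco4 against shco2, and the count called in opposite directions, were added after the data were seen.

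The rule for named genes took, among probe sets with 1 symbol called with both hairpins in the same direction and with every hairpin array beyond every scramble array, the 12 genes with the largest smaller fold change up and the 12 down; for shco4 against shco2, likewise, the 8 largest differences each way; from each list up to 4 members with the smallest p in the mean of both hairpins; and, whatever their values, a set of genes that includes DAND5, ID1, ID3, SMAD7, SOX2, NANOG, POU5F1, WWTR1, CD44 and ALDH1A3. For 415 genes up and 374 down, and for 2154 and 2547 genes between the hairpins, the conditions of the rule were met. Single arrays were left out in turn for genes taken by this rule, in the comparisons of each hairpin with scramble and, for the genes named for it, between the hairpins, and for the called members of lists in all 4 comparisons at the probe set taken for the list. Deviations from the group means of arrays with the same replicate number correlated at 0.133 to 0.235 between scramble and shco4, at 0.0571 to 0.29 between scramble and shco2 and at 0.0576 to 0.213 between the hairpins. Each array correlated best with its own number in the other lines, in 18 of 18 cases tested. Whether the numbers mark pairs was judged by correlation alone. The main model left the replicate number out in every comparison. It was fitted as a block only as an alternative, across all lines.

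The model was tested on simulated data with 66, 67 and 67 changed probe sets at log2 changes of 0.5, 1 and 2. For shco2 against scramble it called 17, 38 and 65 of them (25.8%, 56.7% and 97%). It also made 15 false calls among 22015 unchanged. The false share of all its calls was thus above the adjusted p threshold in this simulation. The alternatives tried were quantile normalization, median centring, dim probe sets left out (the lowest 40%), probe sets at the floor on all arrays left out, the replicate number as a block, only the 2 groups compared, a trend and robust prior, array weights, a floor of 64, log2(value + 1), 1 probe set per gene, an adjusted p under 0.01, a 2-fold minimum, both hairpins as 1 group of 6, and each array left out in turn. Other splits of the arrays were fitted as well. DAND5 and POU5F1 were left out because the annotation names no probe set for them.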

Results

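Gene expression was measured in MDA-MB-231, a human triple-negative breast cancer cell line, on 9 Affymetrix 3′ expression arrays. The cells had been stably transduced with lentiviral vectors that encode a control hairpin (scramble) or 1 of 2 hairpins against Coco, called shco2 and shco4, with 3 biological replicates in each of the 3 groups. Coco, the product of the gene DAND5, is a secreted protein that binds and blocks ligands of the BMP, Nodal and activin family. Median intensity per array lay between 122 and 130 after the authors' scaling, and 3 arrays per group limit the precision of every value below. The comparisons ask how expression differs between cells with either Coco hairpin and cells with the control hairpin, whether the 2 hairpins give the same changes, and how they differ from each other.

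The 3 lines formed 3 separate groups of arrays. Pearson r across probe sets, which are not independent replicates, was 0.986 to 0.992 between arrays of 1 line, 0.971 to 0.980 between scramble and shco2, 0.971 to 0.979 between scramble and shco4, and 0.960 to 0.968 between shco2 and shco4. The first principal component, with 46.5% of the variance, had the hairpins at its opposite ends and scramble between them, and the second, with 20.3%, set scramble apart from both. The ratio of 3′ to 5′ signal, a sign of RNA integrity, was 1.08 ± 0.016 for ACTB in scramble, 1.10 ± 0.015 with shco2 and 1.13 ± 0.0086 with shco4 (SD, n = 3 each), and for GAPDH it was 0.899 ± 0.051, 0.914 ± 0.032 and 0.892 ± 0.011.

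**Figure D1:**
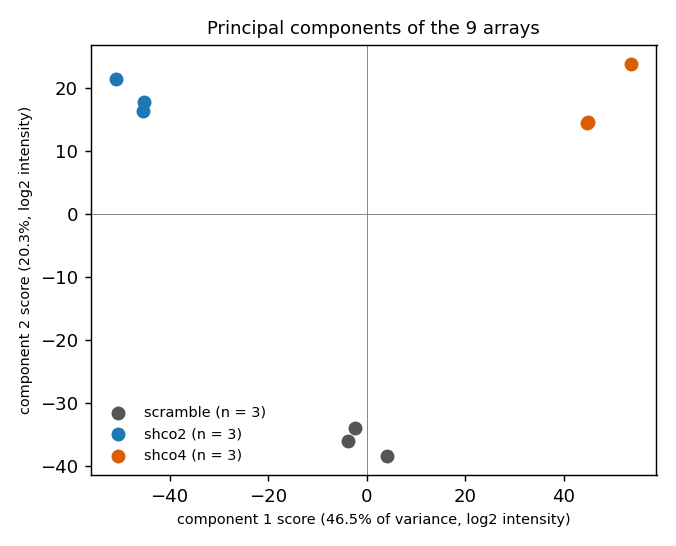
Scores of the 9 arrays on the first and second principal components of log2 intensity, 1 point per array, coloured by line. Component 1 (46.5% of the variance) separates shco2 from shco4, and component 2 (20.3%) separates scramble from both.

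The level of Coco itself could not be read: 0 probe sets carried the symbol DAND5 in the annotation used here, so the degree of knockdown was not analysed here. POU5F1 was unnamed as well. Among the genes followed whatever their values, ALDH1A3, an aldehyde dehydrogenase used as a stem cell marker, fell with shco2 by 1.66 ± 0.19 on the log2 scale (SE, n = 3; adjusted p = 0.00206) and differed from scramble by -0.11 with shco4 (adjusted p = 0.816). CD44, a surface receptor for hyaluronan, had 8 probe sets. The pair with the largest changes fell with shco2 by 0.88 and 1.17, and all 8 were higher with shco4 than with shco2, by 0.73 to 1.37. ID1, a transcriptional regulator induced by BMP, differed by -0.84 with shco2 and -0.67 with shco4 and did not pass (adjusted p = 0.115 and 0.206), but passed with the replicate number as a block (adjusted p = 0.0158 and 0.0314). ID3 differed by 0.23 and -0.33 and did not pass. SMAD7, an inhibitor of TGF-beta family signalling, did not pass with either hairpin (-0.47 and 0.73), although the difference with shco4 passed in the blocked fit (adjusted p = 0.0195). It was higher with shco4 than with shco2 (mean log2 intensity 8.70 and 7.49, n = 3 each, adjusted p = 0.0054). SOX2 lay near the floor on all arrays, and NANOG lay at the floor in all 3 groups.

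WWTR1, which encodes the transcriptional coactivator TAZ, differed with shco4 at its 3 probe sets by -0.65 (adjusted p = 0.02), -1.32 (adjusted p = 0.0351) and -0.57 (adjusted p = 0.0427), and with shco2 by -0.30, -0.91 and -0.17, which did not pass. With the replicate number as a block, the second probe set passed with shco2 (adjusted p = 0.01745). The shco4 call of the first probe set ended without scramble replicate 2 (adjusted p = 0.0534), shco4 replicate 1 (0.0578) or shco4 replicate 2 (0.0591). That of the second ended without scramble replicate 1 (0.0542), 2 (0.105) or 3 (0.1), shco2 replicate 3 (0.0622), or shco4 replicate 1 (0.0779) or 2 (0.082). That of the third ended without scramble replicate 1 (0.116), 2 (0.118) or 3 (0.0863), shco2 replicate 1 (0.0615), or shco4 replicate 1 (0.122), 2 (0.0875) or 3 (0.0731), and in the fit with the replicate number as a block (0.0724).

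A set of genes changed the same way with both hairpins. HSD17B10, a mitochondrial dehydrogenase, rose by 1.93 ± 0.06 with shco2 and 2.00 ± 0.06 with shco4 on the log2 scale (SE, n = 3), or 3.81-fold and 4.00-fold. CEMIP, a protein that takes part in the breakdown of hyaluronan, fell by 3.38 ± 0.15 and 3.37 ± 0.15, or 10.4-fold and 10.3-fold. COL6A3, a chain of collagen VI, fell by 3.12 ± 0.17 and 2.33 ± 0.17. TGM2, a transglutaminase that crosslinks proteins, fell by 1.67 and 1.71. PLAT, the tissue plasminogen activator, fell by 1.75 and 1.86, and CDCP1, a transmembrane glycoprotein, fell by 1.78 and 1.92.

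Other genes that rose with both hairpins were IP6K2, an inositol hexakisphosphate kinase (1.51 and 1.33), TOLLIP, an adaptor of Toll-like receptor signalling (1.34 and 1.32), GPR137 (1.51 and 1.77) and MPPE1 (2.39 and 2.04, but 1.14 and 0.79 with a floor of 64 in place of 16). Other genes that fell with both were FNDC4 (-2.19 and -2.80, but -0.87 and -0.87 with that floor), OLFML2A (-2.57 and -1.78) and CCDC68 (-2.14 and -1.72). LAPTM5, a lysosomal membrane protein, fell by 2.57 and 2.00. GGT5, a gamma-glutamyltransferase, was at the floor on all 6 arrays of the hairpin lines, at least 7.69-fold below scramble. SLC2A11 rose (1.16 and 1.47) and TRBC1 fell (-1.66 and -1.67), but with a floor of 64 neither gene passed with either hairpin. Of the 24 genes that the rule for named genes took here, 17 kept both calls with each array left out in turn, and the other 7, which include 6 of the 12 that rose, are not described singly.

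With both hairpins, 1020 of 22215 probe sets were called in the same direction, 523 up and 497 down, from 788 genes, and 741 were called in opposite directions. The test was limma at an adjusted p under 0.05 for each hairpin. Calls drawn independently would give 215 shared up and 216 shared down, and 232 and 200 in the opposite directions (up with shco2 and down with shco4, observed 401, and the reverse, observed 340). The log2 fold changes of the hairpins had a Pearson r of 0.135 across probe sets (Spearman rho 0.125). Simulated groups without any effect, with controls shared in the same way, gave r = 0.5 on average and a covariance of 0.0223, against an observed covariance of 0.0317. The excess was 0.0495 of the geometric mean of the hairpins' variances minus error. The simulation gave at most 1 shared call, but without effects hardly any probe set is called. It thus does not show the overlap of 2 unrelated sets of calls that share controls. The scramble arrays stand in both comparisons, so a change shared by both hairpins cannot be told from a change particular to the scramble line. The same-direction count was 670 and 668 without scramble replicates 1 and 2, and the opposite-direction count was 416, 412 and 434 without scramble replicates 1, 2 and 3 and 479 without shco2 replicate 3.

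**Figure D2:**
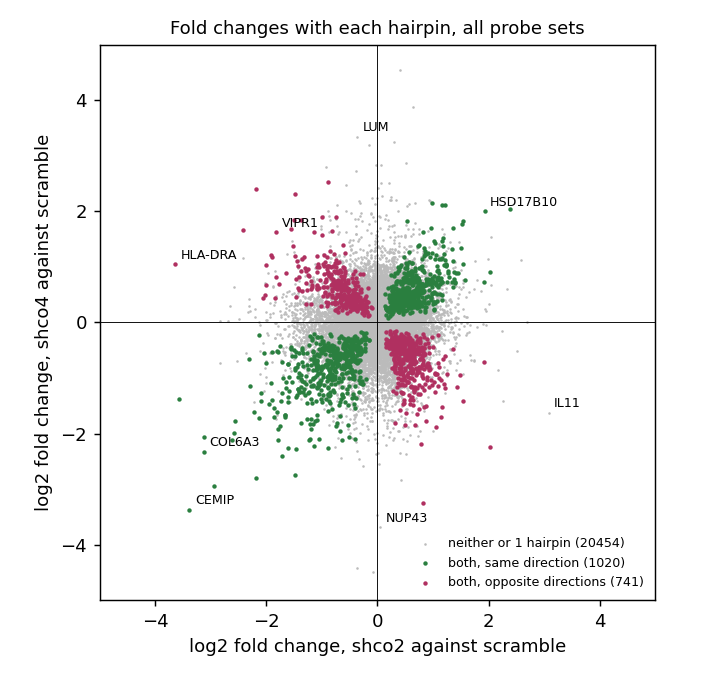
Log2 fold change against scramble with shco2 (x axis) and shco4 (y axis), 1 point per probe set. Green marks the 1020 probe sets called with both hairpins in the same direction and purple the 741 called in opposite directions.

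**Figure D3:**
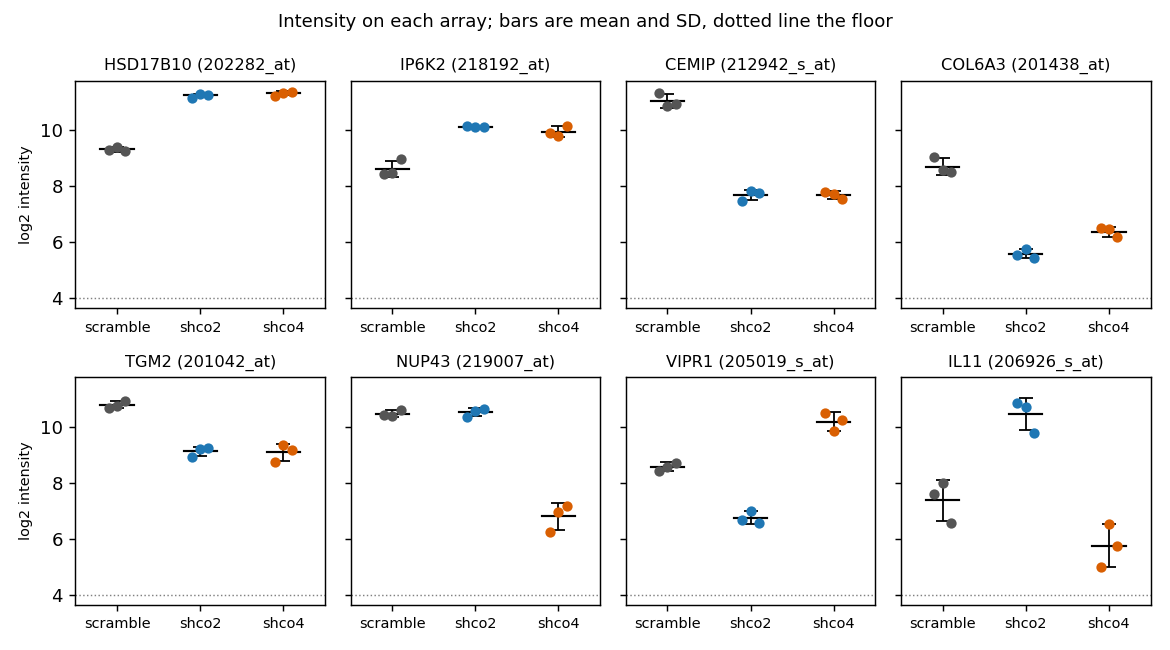
Log2 intensity of 8 genes on each of the 9 arrays, with mean and SD per line (n = 3) and the floor as a dotted line. CEMIP, COL6A3 and TGM2 fell and HSD17B10 and IP6K2 rose with both hairpins, while NUP43, VIPR1 and IL11 differed between them.

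With shco2, genes for the extracellular matrix and for adhesion were lower than in scramble. LOXL2, which crosslinks collagen, fell by 2.13 ± 0.05 on the log2 scale (SE, n = 3), COL1A2, a chain of collagen I, by 2.36 ± 0.24, and FN1, fibronectin, by 1.64 ± 0.23. Of 30 extracellular matrix and collagen genes, 16 fell and 0 rose (19 fell adjusted over the list alone), with a median of -0.82 (camera adjusted p = 2.81e-06; adjusted p = 0.0404 with an estimated correlation). Of 25 integrin and focal adhesion genes, 11 fell and 0 rose (14 adjusted over the list alone), among them ITGA6 (-1.81), ITGA3 (-1.37) and CAV1, caveolin (-1.37), with adjusted p = 2.81e-06 and adjusted p = 0.0316 with an estimated correlation. Of 19 mesenchymal genes, 11 fell and 0 rose (12 adjusted over the list alone), among them S100A4 (-1.25), COL5A1 (-1.18) and SNAI2, a transcription factor of epithelial-mesenchymal transition (-0.83). This list had adjusted p = 2.92e-05 and adjusted p = 0.0333 with an estimated correlation. As fixed, it shares FN1, SPARC, COL5A1, COL6A1, TNC and LOX with the extracellular matrix list, and ITGB1 and ITGA5 with the integrin list. The calls of these lists are thus not independent, here, in the mean of both hairpins or between the hairpins. Of 28 matrix proteases and inhibitors, 9 fell and 2 rose (9 and 3 adjusted over the list alone), among them TIMP3, an inhibitor of metalloproteinases (-1.51), with adjusted p = 0.0128 and adjusted p = 0.207 with an estimated correlation.

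Keratins and other epithelial genes were also lower with shco2. Of 22 epithelial genes, 9 fell and 1, OCLN, rose (10 and 1 adjusted over the list alone), among them KRT7 (-1.22), KRT18 (-0.86) and KRT8 (-0.80), with adjusted p = 0.00215 and adjusted p = 0.0939 with an estimated correlation. Of 15 luminal breast line genes, the markers of another kind of breast cell, 7 fell and 0 rose (8 adjusted over the list alone), with adjusted p = 0.000802 and adjusted p = 0.0756 with an estimated correlation. This list shares KRT8, KRT18 and KRT19 (-1.19) with the epithelial list. Of 22 hypoxia and glycolysis genes, 13 fell and 1, ADM, rose (16 and 1 adjusted over the list alone), among them NDRG1, a stress-responsive gene (-1.64), and the glycolytic enzyme TPI1 (-0.51), with adjusted p = 1.12e-05 and adjusted p = 0.0939 with an estimated correlation. Of 13 MHC class I and antigen presentation genes, 7 fell and 0 rose (8 adjusted over the list alone), among them the peptide-trimming enzyme ERAP1 (-1.12), with adjusted p = 0.000298 and adjusted p = 0.294 with an estimated correlation. Of 15 cholesterol synthesis genes, 5 fell (MSMO1, LSS, INSIG1, DHCR7 and SREBF2) and 1 rose, the same numbers as adjusted over the list alone, with adjusted p = 0.00801 and adjusted p = 0.458 with an estimated correlation. The INSIG1 call ended without shco2 replicate 1 (adjusted p = 0.051). The calls of OCLN, MSMO1 and DHCR7 ended with 4, 6 and 6 of the 9 arrays left out in turn (highest adjusted p 0.065 without shco2 replicate 1, 0.0919 without shco2 replicate 1 and 0.103 without shco2 replicate 2).

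With shco2, BMP4, a BMP ligand, fell by 2.00 ± 0.11 (4.00-fold), SMAD3, a mediator of TGF-beta signals, by 0.90, the receptor TGFBR2 by 0.66 and the corepressor TGIF1 by 0.61. LEF1, a transcription factor of the Wnt pathway, rose by 1.90 ± 0.22, ACTA2, smooth muscle actin, by 1.93 and the cytokine IL6 by 1.13. Of 12 Wnt target genes, 5 fell (DKK1, CD44, CCND1, BMP4 and FZD7) and 1, LEF1, rose, as when adjusted over the list alone, with adjusted p = 0.00342 and adjusted p = 0.0756 with an estimated correlation. The DKK1 call ended without scramble replicate 1 (adjusted p = 0.054) or shco2 replicate 1 (0.0532) or 3 (0.0593). The CCND1 call ended with 6 of the 9 arrays left out in turn (highest 0.0809, without shco2 replicate 1). Of 16 stem cell and pluripotency genes, 6 fell and 1, HMGA2, a chromatin protein (0.74), rose, as when adjusted over the list alone, with adjusted p = 0.0148 and adjusted p = 0.0939 with an estimated correlation.

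The lists that were higher with shco2 were those of replication and p53. Of 27 G1/S and replication genes, 5 rose (SLBP, FEN1, RFC4, CCNE2 and CHAF1B) and 0 fell (4 rose adjusted over the list alone), with a median of 0.39, adjusted p = 0.000573 and adjusted p = 0.458 with an estimated correlation. The SLBP call ended without scramble replicate 1 or 3 or shco2 replicate 2 or 3 (adjusted p up to 0.061). The FEN1 call ended without scramble replicate 1 or 2 or shco2 replicate 2 or 3 (up to 0.0564). The RFC4 call ended without scramble replicate 1 or 3 or shco2 replicate 1 or 3 (up to 0.0632). The CCNE2 call ended with each array but scramble replicate 3 and shco4 replicate 1 left out (up to 0.134). Of 14 p53 target genes, 5 rose (CDKN1A, TP53I3, XPC, DDB2 and MDM2) and 0 fell (6 rose adjusted over the list alone), with a median of 0.62, adjusted p = 0.00953 and adjusted p = 0.108 with an estimated correlation. The DDB2 call ended without scramble replicate 3 (adjusted p = 0.0527). Over all probe sets, 4589 of 22215 were called with shco2 (2379 up, 2210 down, from 3297 genes), of which 309 rose and 711 fell at least 2-fold. Of the 27 lists 13 were called by camera, 2 up and 11 down, and 3 stayed called with an estimated correlation.

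With shco4, genes for DNA replication were lower than in scramble. GINS1, a part of the replicative helicase, fell by 2.37 ± 0.22 on the log2 scale (SE, n = 3), ORC1, a subunit of the origin recognition complex, by 2.13 ± 0.19 (1.05 with a floor of 64), CDC6, a loader of the helicase, by 1.77 ± 0.14 and UNG, a DNA glycosylase, by 0.80 ± 0.03. Of 27 G1/S and replication genes, 21 fell and 0 rose (25 fell adjusted over the list alone), with a median of -1.17, adjusted p = 6.67e-14 and adjusted p = 0.417 with an estimated correlation. Of 30 G2/M and mitosis genes, 6 fell and 0 rose, as when adjusted over the list alone, with a median of -0.35, adjusted p = 0.00149 and adjusted p = 0.645 with an estimated correlation. The cell cycle inhibitor CDKN1B rose by 1.15 ± 0.14.

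Of 27 interferon-stimulated genes, 12 fell and 4 rose with shco4 and 11 did not pass (13 and 4 adjusted over the list alone), with adjusted p = 0.00357 and adjusted p = 0.55 with an estimated correlation. IFIT3 (-1.91), IFIT2 (-1.78) and IFI44 (-1.61) fell. The 4 that rose were IFI27, IFI6, IRF7 and MX1, an antiviral GTPase (0.70). The IFI27 call ended with 5 of the 9 arrays left out in turn (highest adjusted p 0.0767, without shco4 replicate 1) and with the replicate number as a block (0.0637), and the IFI6 call with 7 (0.114, without scramble replicate 2). AXL, a receptor tyrosine kinase, fell by 2.11 ± 0.11, and PLAU, the urokinase plasminogen activator, by 1.83 ± 0.21. AXL stands among 22 YAP and TAZ target genes, of which 8 fell and 1, ARHGEF17, rose (10 and 2 adjusted over the list alone), with adjusted p = 0.019 and adjusted p = 0.453 with an estimated correlation. Of 20 ATF4 and integrated stress response genes, 8 fell and 0 rose (9 adjusted over the list alone), among them ASNS, asparagine synthetase (-0.72), and the lipoprotein receptor VLDLR (-0.82), with adjusted p = 0.00483 and adjusted p = 0.324 with an estimated correlation. Of 22 hypoxia and glycolysis genes, 9 fell and 0 rose (10 adjusted over the list alone), among them NDRG1 (-1.17) and the mitophagy receptor BNIP3 (-1.02), with adjusted p = 0.00483 and adjusted p = 0.453 with an estimated correlation. Of 25 integrin and focal adhesion genes, 6 fell and 1, ILK, rose, as when adjusted over the list alone, among them ITGA5 (-1.37) and ITGB5 (-0.78), with adjusted p = 0.0238 and adjusted p = 0.324 with an estimated correlation. The integrin call ended without scramble replicate 3 (adjusted p = 0.074). The ILK call ended without shco4 replicate 2 (0.0529) and the ARHGEF17 call with 8 of the 9 arrays left out in turn (highest 0.136, without scramble replicate 2).

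Cholesterol synthesis genes were the list that rose with shco4. Of 15 measured, 7 rose and 0 fell (10 rose and 1 fell adjusted over the list alone), among them NSDHL (0.89) and IDI1 (0.64), with a median of 0.63, adjusted p = 0.00149 and adjusted p = 0.504 with an estimated correlation. Other single genes that rose were LUM, the matrix proteoglycan lumican (3.34 ± 0.31, but 1.70 with a floor of 64), FSCN1, an actin-bundling protein (2.21), INHBB, a subunit of activin B and inhibin B (1.93), BHLHE41, a circadian transcription factor (1.38), and the immunoproteasome subunits PSMB8 (0.95) and PSMB9 (0.89). DDB2, a DNA damage binding protein, fell by 1.48, and EPCAM, an epithelial adhesion molecule, fell as well (-1.30). TAPBP, the chaperone tapasin, was called in both directions, lower by 1.47 at 1 probe set and higher by 1.02 at another (adjusted p = 0.0499). Over all probe sets, 4178 were called with shco4 (2011 up, 2167 down, from 2989 genes), of which 341 rose and 609 fell at least 2-fold. The count was 2760 without scramble replicate 2. Of the 27 lists 8 were called by camera, 1 up and 7 down, none with an estimated correlation, and 5 were called when dim probe sets were left out.

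The mean of both hairpins was then set against scramble, in which a change of the hairpin lines cannot be told from a change particular to the scramble line. Along with the genes called in each hairpin, ITGB5, an integrin subunit, fell by 0.76 on the log2 scale, BHLHE40, a transcription factor of the TGF-beta target list, by 1.13, NDRG1 by 1.41, DOCK5, an exchange factor for Rac, by 1.16 and TPI1 by 0.42. HMGA2 rose by 0.86 and NFKB1, a subunit of NF-kB, by 0.64. Of 25 integrin and focal adhesion genes, 9 fell and 0 rose (13 adjusted over the list alone), with adjusted p = 1.75e-06 and adjusted p = 0.0258 with an estimated correlation. Of 22 hypoxia and glycolysis genes, 14 fell and 1, ADM, rose (16 and 1 adjusted over the list alone), with adjusted p = 1.75e-06 and adjusted p = 0.102 with an estimated correlation. In the comparisons of single hairpins, 6 of these 22 fell with both. Of the 25 integrin and focal adhesion genes, 3 fell with both, and 1 fell with shco2 and rose with shco4.

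Of 30 extracellular matrix genes, 10 fell and 0 rose in the mean of both hairpins (14 adjusted over the list alone; adjusted p = 1.99e-05, and adjusted p = 0.0924 with an estimated correlation). Of 19 mesenchymal genes, 6 fell and 0 rose (11 adjusted over the list alone; adjusted p = 0.00312, and adjusted p = 0.0924 with an estimated correlation). Of 22 epithelial genes, 7 fell and 0 rose (9 adjusted over the list alone; adjusted p = 0.00138, and adjusted p = 0.102 with an estimated correlation). Of 15 luminal breast line genes, 4 fell (KRT18, KRT8, KRT19 and ERBB3) and 0 rose (5 adjusted over the list alone; adjusted p = 0.0176, and adjusted p = 0.158 with an estimated correlation). Of 22 YAP and TAZ target genes, 7 fell and 0 rose (8 and 1 adjusted over the list alone; adjusted p = 0.0133, and adjusted p = 0.246 with an estimated correlation). Of 27 G1/S and replication genes, 6 fell and 0 rose (8 adjusted over the list alone, adjusted p = 1.99e-05, and adjusted p = 0.467 with an estimated correlation). That list was higher with shco2 and lower with shco4. Singly, 0 replication genes fell with both hairpins, and 3 rose with shco2 and fell with shco4. Likewise 3 extracellular matrix, 1 mesenchymal, 1 epithelial, 1 YAP and TAZ target and 0 luminal genes fell with both. 1 mesenchymal and 1 luminal gene fell with shco2 and rose with shco4.

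The remaining calls of lists in the mean of both hairpins did not hold with each array left out. Of 16 stem cell and pluripotency genes, 4 fell (ITGA6, SNAI2, WWTR1 and ALDH1A3) and HMGA2 rose (5 and 1 adjusted over the list alone; adjusted p = 0.0391, and adjusted p = 0.158 with an estimated correlation), and the call ended without scramble replicate 2 (0.0765) or 3 (0.0669), shco2 replicate 2 (0.0564) or shco4 replicate 2 (0.0644). The single calls of ALDH1A3 and WWTR1 ended with 2 and 8 of the 9 arrays left out in turn (highest 0.0654 without scramble replicate 2 and 0.149 without scramble replicate 3). Of 30 G2/M and mitosis genes, KIF11 fell and HMMR rose (0 and 1 adjusted over the list alone; adjusted p = 0.0203, and adjusted p = 0.792 with an estimated correlation), and the call ended without scramble replicate 2 (0.204) or shco4 replicate 1 (0.0742). Of 28 matrix proteases and inhibitors, 6 fell and ADAM17 and MMP15 rose (8 and 2 adjusted over the list alone; adjusted p = 0.0391, and adjusted p = 0.302 with an estimated correlation), and the call ended without scramble replicate 3 (0.0924), shco2 replicate 1 (0.0605) or 3 (0.0508), or shco4 replicate 1 (0.0692) or 2 (0.0504). The single calls of KIF11, HMMR, ADAM17 and MMP15 ended with 5, 3, 6 and 3 of the 9 arrays left out in turn (highest 0.119 without scramble replicate 2, 0.0727 without scramble replicate 3, 0.124 without scramble replicate 1 and 0.0721 without scramble replicate 2). Over all probe sets, 3136 were called (1494 up, 1642 down, from 2312 genes), of which 110 rose and 237 fell at least 2-fold. The count was 1915, 1824 and 2003 without scramble replicates 1, 2 and 3, and 670 when the 6 hairpin arrays were fitted as 1 group. In all, 11 lists were called by camera, each of them down. Singly, 0 stem cell, 0 mitosis and 2 matrix protease genes fell with both hairpins.

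The 2 hairpin lines differed from each other at more probe sets than either did from scramble. 1 probe set of HLA-DRA, an MHC class II chain, was at the floor on the 3 shco2 arrays and at least 25.8-fold higher with shco4. Another, above the floor with shco2, was higher by 4.17 on the log2 scale. CRTAM, a receptor of T and natural killer cells, CFP, properdin of the complement system, and LUM were at the floor with shco2 as well, and were higher with shco4 by at least 4.59, 4.08 and 3.70 on the log2 scale. RGCC, a regulator of the cell cycle, was higher with shco4 by 3.80 on the log2 scale, MFNG, a glycosyltransferase that acts on Notch, by 3.72 and PPFIBP2 by 3.57 (2.32 with a floor of 64). The shco2 arrays of RGCC and MFNG lay under an intensity of 64 as well, so their differences too are smaller with that floor. VIPR1, a receptor for vasoactive intestinal peptide, was higher by 3.44 ± 0.19 (SE, n = 3), having fallen by 1.82 with shco2 and risen by 1.62 with shco4.

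IL11, a cytokine of the IL6 family, was lower with shco4 than with shco2 by -4.70 ± 0.55 (SE, n = 3), and had risen by 3.08 with shco2. The gene lists read IL11 at another probe set. NUP43, a nuclear pore protein, was lower by -3.73 ± 0.24, having fallen by 3.68 with shco4 and differed from scramble by 0.05 with shco2. KISS1, a metastasis suppressor and the precursor of kisspeptin, was lower with shco4 by -2.96 (-1.11 with a floor of 64), CCNE2, cyclin E2, by -2.94, PDGFRL by -3.02 (-1.82 with that floor), PLCXD1 by -2.95 and the pseudogene OR7E37P by -2.97. SUSD5 was at the floor with shco4, at least 8.14-fold below shco2. Over all probe sets, 6881 differed (3299 higher and 3582 lower with shco4, from 4638 genes), 1147 and 1150 of them at least 2-fold. With 1 probe set per gene the number was 4379 of the genes tested.

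Gene lists set the hairpins apart in both directions. Of 27 G1/S and replication genes, 26 were lower and 0 higher with shco4 than with shco2, as when adjusted over the list alone, with a median of -1.50, among them GINS1 (-2.88) and ORC1 (-2.67), with adjusted p = 1.24e-12 and adjusted p = 0.177 with an estimated correlation. Of 27 interferon-stimulated genes, 14 were lower and 5 higher, as when adjusted over the list alone, among them IFIT2 (-2.06), with adjusted p = 0.00683 and adjusted p = 0.406 with an estimated correlation. Of 14 p53 target genes, 6 were lower and 0 higher (8 adjusted over the list alone), among them DDB2 (-2.12), with adjusted p = 0.00417 and adjusted p = 0.128 with an estimated correlation. Of 20 ATF4 and integrated stress response genes, 13 were lower and 2, DDIT4 and CTH, higher (14 and 2 adjusted over the list alone), with adjusted p = 0.00187 and adjusted p = 0.128 with an estimated correlation. Of 30 G2/M and mitosis genes, 10 were lower and 0 higher, as when adjusted over the list alone, with adjusted p = 0.012 and adjusted p = 0.595 with an estimated correlation, and that call ended without shco4 replicate 1 (0.0922).

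Of 15 cholesterol synthesis genes, 13 were higher and 1, SC5D, lower with shco4 than with shco2, as when adjusted over the list alone, with a median of 0.97, among them INSIG1 (0.97) and IDI1 (0.82), with adjusted p = 4.31e-05 and adjusted p = 0.213 with an estimated correlation. The INSIG1 call ended with 5 of the 9 arrays left out in turn (highest adjusted p 0.0785, without shco2 replicate 1). SC5D was lower by -0.50 at the probe set taken for the list, a call that ended without shco2 replicate 1 (0.0534) or 2 (0.0538), and higher by at least 1.37 at another, which was at the floor with shco2. Of 30 extracellular matrix genes, 14 were higher and 1, FBN1, lower (16 and 1 adjusted over the list alone), among them LOXL2 (1.90) and COL1A2 (1.81), with adjusted p = 0.000505 and adjusted p = 0.128 with an estimated correlation. Of 13 MHC class I and antigen presentation genes, 10 were higher and 1, TAPBP, lower, as when adjusted over the list alone, with adjusted p = 0.00112 and adjusted p = 0.318 with an estimated correlation. TAPBP was lower by -1.05 at the probe set taken for the list and higher by 0.96 at another (adjusted p = 0.0412). Of 19 mesenchymal genes, 9 were higher and 1, ITGA5, lower, as when adjusted over the list alone, with adjusted p = 0.00186 and adjusted p = 0.128 with an estimated correlation. Of 15 luminal breast line genes, 7 were higher and 1, ERBB3, lower (8 and 1 adjusted over the list alone), with adjusted p = 0.00733 and adjusted p = 0.128 with an estimated correlation.

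The remaining calls of lists between the hairpins did not hold with each array left out. Of 12 Wnt target genes, 6 were higher and 2, MYC and LEF1, lower with shco4, as when adjusted over the list alone, with adjusted p = 0.0159, adjusted p = 0.128 with an estimated correlation, and 0.052 without shco4 replicate 2. The MYC call ended with 7 of the 9 arrays left out in turn (highest 0.139, without shco2 replicate 1). Of 25 integrin and focal adhesion genes, 11 were higher and 3 lower (FERMT2, ITGA5 and SRC), as when adjusted over the list alone, with adjusted p = 0.0327, adjusted p = 0.134 with an estimated correlation, and 0.079 without shco4 replicate 3. The SRC call ended without shco2 replicate 2 (0.0721) or 3 (0.0768) or shco4 replicate 2 (0.0588). Of 14 dormancy-associated genes, 7 were higher and 2, AXL and CDKN1A, lower (8 and 2 adjusted over the list alone), with adjusted p = 0.0327 and adjusted p = 0.192 with an estimated correlation, and the call ended without shco2 replicate 1 (0.0599) or shco4 replicate 2 (0.0727) or 3 (0.0509).

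**Figure D4:**
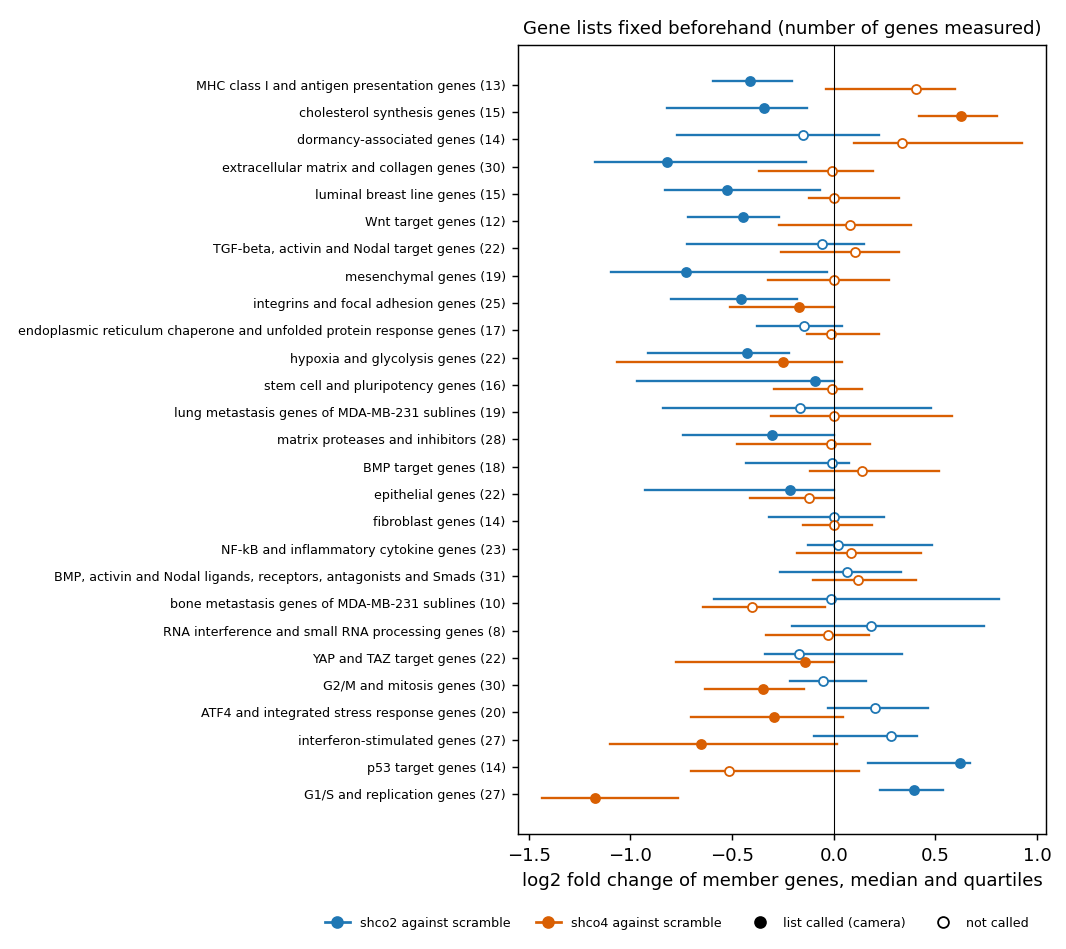
Median log2 fold change against scramble of the measured members of each of the 27 gene lists, with bars from the lower to the upper quartile, for shco2 and shco4. Filled points are lists called by camera; the replication list is at 0.39 with shco2 and -1.17 with shco4.

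Target genes of BMP and of TGF-beta, activin and Nodal were not called as lists by camera in any comparison without a block. With the replicate number as a block, the TGF-beta list was called with shco2 (adjusted p = 0.034) and between the hairpins (0.0445). Fry, which does not compare a list with other genes, called the TGF-beta list with shco2 (adjusted p = 0.00438), in the mean of both (0.0475) and between the hairpins (0.00206), and the BMP list between the hairpins (0.0136). It called the ligand and receptor list with shco4 (0.0205) and between the hairpins (0.00251). Of 18 BMP target genes, 0 passed with shco2 (adjusted p = 0.325), and with shco4 BAMBI, a BMP pseudoreceptor, fell and SMAD6, an inhibitory Smad, rose (adjusted p = 0.387). In the blocked fit, ID1 (0.0158), GATA3 (0.0448) and RUNX2 (0.0332) passed with shco2, each lower. With shco4, ID1 (0.0314, lower) and SMAD7 (0.0195, higher) passed in that fit. The BAMBI call ended without scramble replicate 1 (0.0823) or 2 (0.0789). The SMAD6 call ended without scramble replicate 2 (0.0532) or shco4 replicate 1 (0.0576). Of 22 TGF-beta, activin and Nodal target genes, 6 fell and IL11 rose with shco2 (7 and 1 adjusted over the list alone; adjusted p = 0.0554). With shco4, CCN2, BHLHE40 and IL11 fell and TPM1, JUNB and ANGPTL4 rose (3 and 5 adjusted over the list alone, adjusted p = 0.763). SMAD7 (0.0195, higher) and TAGLN (0.0125, lower) passed as well in the blocked fit with shco4. For the lists, IL11 was read at a different probe set from that described above between the hairpins, so these calls do not belong to the values given there. With 1 array left out, the IL11 call with shco2 at the list's probe set ended for 7 of the 9 arrays (highest adjusted p 0.12, without shco2 replicate 2). With shco4 those of CCN2, IL11, TPM1, JUNB and ANGPTL4 ended for 4, 7, 7, 7 and 4 (highest 0.0659, 0.0989, 0.128, 0.0966 and 0.0891). Of 31 BMP, activin and Nodal ligands, receptors, antagonists and Smads, TGFBR2, BMP4, FST and SMAD3 fell and TWSG1, ACVR1 and ACVR2B rose with shco2 (5 and 3 adjusted over the list alone; adjusted p = 0.835). The FST call ended without scramble replicate 1 (0.0848) or 2 (0.079), shco2 replicate 1 (0.0707) or 3 (0.0734), or shco4 replicate 3 (0.0501). It also ended in the blocked fit (0.0503), where INHBA passed with shco2 (0.0231, higher). The TWSG1 call ended without shco2 replicate 2 (0.0504) and the ACVR1 call with 4 of the 9 arrays left out in turn (highest 0.0857, without shco2 replicate 2). With shco4, TGFBR3 and CHRDL1 fell and ACVR1, INHBB, ACVR2A and BMP2 rose (2 and 4 adjusted over the list alone; adjusted p = 0.266). The calls of TGFBR3, CHRDL1, ACVR1 and ACVR2A ended with 7, 5, 7 and 5 of the 9 arrays left out in turn (highest 0.114, 0.0965, 0.107 and 0.0914), and those of TGFBR3 and CHRDL1 also with the replicate number as a block (0.0614 and 0.0502).

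The metastasis lists hold genes linked to the spread of MDA-MB-231 sublines to lung and bone. Of 19 lung metastasis genes, NEDD9, TNC, MMP1 and VCAM1 fell and EREG and ROBO1 rose with shco2 (5 and 2 adjusted over the list alone; adjusted p = 0.266), and LTBP1 fell and FSCN1, ANGPTL4 and VCAM1 rose with shco4 (1 and 5 adjusted over the list alone; adjusted p = 0.676). Of 10 bone metastasis genes, 2 fell, among them MMP1, and 3 rose, among them DUSP1 and IL11, with shco2, as when adjusted over the list alone (adjusted p = 0.85), and CCN2 and IL11 fell with shco4 (3 adjusted over the list alone; adjusted p = 0.101). Of 14 dormancy-associated genes, NDRG1, SOX9 and CDKN1C fell and CDKN1A rose with shco2 (5 and 1 adjusted over the list alone; adjusted p = 0.18), and AXL, NDRG1 and CDKN1A fell and GAS6, CDKN1B, CDKN1C and BHLHE41 rose with shco4 (3 and 5 adjusted over the list alone; adjusted p = 0.323). Of 23 NF-kB and inflammatory cytokine genes, TNFAIP2, ICAM1 (-0.97) and C3 fell and NFKB1 and IL6 rose with shco2, as when adjusted over the list alone (adjusted p = 0.802), and CCL5 fell and TNFAIP2, NFKB1, IL32 and TNFAIP3 rose with shco4 (1 and 5 adjusted over the list alone; adjusted p = 0.387). Many of these single calls ended with 1 array left out. With shco2 those of TNC, VCAM1, EREG, IL11, CDKN1C and C3 ended for 4, 7, 7, 7, 1 and 8 of the 9 arrays (highest adjusted p 0.0849, 0.104, 0.103, 0.12, 0.0524 and 0.121). With shco4 those of ANGPTL4, VCAM1, CCN2, IL11, CCL5, IL32 and TNFAIP3 for 4, 8, 4, 7, 5, 8 and 6 (highest 0.0891, 0.121, 0.0659, 0.0989, 0.0918, 0.138 and 0.0818). With the replicate number as a block VCAM1 did not pass with shco4 (0.0588). Fry called the dormancy list with shco2 (adjusted p = 0.0114), the bone metastasis list with shco4 (0.0238) and the NF-kB list with shco4 (0.0275) and in the mean of both (0.0272). Between the hairpins it called the lung metastasis (0.0124), bone metastasis (0.0136) and dormancy (0.00351) lists.

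Of 17 endoplasmic reticulum chaperone and unfolded protein response genes, PDIA6, CALR and XBP1 fell and 1 rose with shco2, as when adjusted over the list alone (adjusted p = 0.154), and PDIA6 and HERPUD1 rose with shco4 (1 adjusted over the list alone; adjusted p = 0.858). The CALR call ended without scramble replicate 1 (0.0527), and the XBP1 call without scramble replicate 2 (0.0578) or shco2 replicate 1 (0.0586). The PDIA6 call ended with 5 of the 9 arrays left out in turn with shco2 and 6 with shco4 (highest 0.0897 and 0.117), and with shco4 also with the replicate number as a block (0.0552). The HERPUD1 call ended without scramble replicate 1 (0.0513) or 2 (0.0575). Of 14 fibroblast genes, the markers of another cell type, COL1A2 fell and ACTA2 rose with shco2 (adjusted p = 0.802), and LUM rose with shco4 (adjusted p = 0.74). Of 8 RNA interference genes, AGO4 fell and TARBP2, AGO1 (0.85) and AGO3 rose with shco2, as when adjusted over the list alone (adjusted p = 0.41), and 2, among them TARBP2, fell and 1 rose with shco4 (3 and 1 adjusted over the list alone; adjusted p = 0.74). The AGO3 call with shco2 and the TARBP2 call with shco4 each ended with 4 of the 9 arrays left out in turn (highest 0.0789 and 0.0874). With a floor of 64, MMP1 of the metastasis lists and AGO4 did not pass with shco2. The BMP, TGF-beta, ligand and receptor, lung metastasis, bone metastasis, NF-kB, endoplasmic reticulum, fibroblast and RNA interference lists were not called by camera in any of the 4 comparisons without a block. Fry called the fibroblast list with shco4 (0.037) and between the hairpins (0.00243), and the RNA interference list with shco2 (0.0202) and between the hairpins (0.00361). Members outside the rule for named genes were named here and above after their values were seen, because 5 or fewer had passed. The median, the mean and the test of a list differed in sign for the ligand and receptor, bone metastasis and fibroblast lists with shco2, for the TGF-beta, mesenchymal, endoplasmic reticulum and luminal lists with shco4, and for the lung metastasis and dormancy lists in the mean of both hairpins, none of them called there by camera.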

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

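Both tests of the replication pattern, the test of 1 line set apart, the tests of opposite probe sets with each hairpin singly, the 95% limits and the count of opposite directions itself were chosen only after the result was seen; the other tests were written before it.

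3 results were picked out because the effects of the 2 hairpins differ. The first is the 741 probe sets called in opposite directions with shco2 and shco4. Each of the 741 was also called for shco4 against shco2, but this is no separate test. Opposite changes give a difference larger than either, with the same SE in this fit, so that call follows from the selection. The G1/S and replication genes had a median log2 difference of -1.50 between shco4 and shco2 (camera adjusted p = 1.24e-12, but adjusted p = 0.177 with an estimated correlation). The cholesterol synthesis genes had a median log2 difference of 0.97 (camera adjusted p = 4.31e-05, but adjusted p = 0.213 with an estimated correlation).

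More probe sets differed between the 2 hairpin lines than between either and scramble, 6881 against 4589 at most. Between-array scaling is argued against, since the ratio of these counts stayed at 1.47 or more under quantile normalization and median centring, and so is 1 aberrant array, since the lowest ratio with an array left out was 1.34. Regional differences such as copy number between the lines are argued against as the main cause: after running medians of 51 neighbouring genes had been subtracted, 4377 genes were called against 4425 before (0.989 of that number), 3995 of them both before and after, although neighbours did move together slightly more than in permuted order (SD ratio 1.18, p = 0.000999, the smallest that 1000 permutations can give). The count of probe sets that set scramble apart from both other lines (1020) was 0.353 of the lower of the counts that set shco2 (3197) or shco4 (2888) apart, which argues against a shared effect of both hairpins as the main difference among the 3 lines. Off-target effects of each hairpin, different degrees of knockdown and the separate history of each transduced line stay open, since Coco could not be measured and each hairpin stands for 1 line.

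Of 27 replication genes, 21 fell with shco4 (adjusted p = 0.417 with an estimated correlation) and 5 rose with shco2 (adjusted p = 0.458 with an estimated correlation). Between-array scaling is argued against, because the list's median lay at -1.17 from the median of 10000 drawn sets of other genes matched in intensity, none of which was as low (lowest -0.41, and -0.38 with quantile normalization). With fewer dividing cells as the whole cause, an equal fall of replication and mitosis genes was predicted. Replication genes fell further (medians -1.17 and -0.35, difference -0.826, permutation p = 1e-05, the smallest that 100000 permutations can give). The permutation exchanges genes, which may move together, so its p does not measure the spread between arrays or lines. Whether fewer dividing cells lower both lists equally was not tested, so this cause stays open. A change in the length of cell cycle phases, and an off-target effect of shco4, may contribute and were not tested.

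Some genes had probe sets called in opposite directions, 68 of 1120 genes with several called probe sets between the hairpins, 30 of 645 with shco2 and 20 of 587 with shco4. With cross-hybridizing probe sets as the main cause, identifiers that mark shared sequence were predicted to be more frequent among these genes. With shco2 they were less frequent than among genes called 1 way. The shares were 66.7% and 85.0%, a difference of -18.4 points (Fisher exact p = 0.0169). The count pools all lettered suffixes and does not tell sequence shared by transcripts of 1 gene from sequence shared with other genes. Cross-hybridizing probe sets thus stay open with shco2. They stay open also between the hairpins (77.9% and 83.7%, -5.80 points, Fisher exact p = 0.238) and with shco4 (80% and 79.9%, 0.106 points, Fisher exact p = 1). Dim probe sets near the floor are argued against as the main cause between the hairpins, where 0.147 of these genes had one (95% limits 0.0728 to 0.254; 0.0951 of genes called 1 way), and with shco2 (0.1, limits 0.0211 to 0.265; 0.0764), and stay open with shco4 (0.2, limits 0.0573 to 0.437; 0.0564). Different transcripts of 1 gene stay open and were not tested.

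Other splits of the arrays were fitted in the same way. For shco2 against scramble, 1 of the 10 splits of 6 arrays into 3 and 3 gave as many calls, the real one (4342, highest other 1), and likewise 1 of 10 for its lists (13, highest other 7). For shco4 it was 1 of 10 for calls (2906, highest other 2) and 1 of 10 for lists (8, highest other 7), and between the hairpins 1 of 10 for calls (6003, highest other 4). These splits are too few for a share under 0.05. With both hairpins as 1 group of 6, 3 of 84 splits gave as many calls as the real one (670); the others set shco2 (3812) or shco4 (3473) apart, and no split that mixed lines gave more than 14. For the gene lists of that fit, 41 of 84 splits called at least as many as the real split (6, highest other 15), so chance was not excluded for them. For probe sets called with both hairpins in the same direction, 5 of 100 drawn splits gave at least the 1020 of the real one (highest 1988), so chance was not excluded by that share; the 4 others all used the 3 arrays of 1 hairpin line as the reference, and the 95 with a mixed reference gave at most 3.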

How the results depend on the processing

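The settings that leave out probe sets at the floor on all arrays, the counts in opposite directions and the lists between the hairpins were chosen only after the result was seen; the others were planned. None of the values of named genes that were called in the main fit or in the setting changed sign in the settings run on them. Changes of sign in values called in neither were not counted. There were 322 values, but 284 without dim probe sets, 285 with 1 probe set per gene and 320 without those at the floor. The 2-fold minimum, the adjusted p under 0.01 and the group of 6 were not run on them. Of the 24 genes named for both hairpins, 31 of 48 calls held in each of the settings run. With the replicate number as a block (replicate block) the counts were 5345 for shco2, 4913 for shco4, 3824 for the mean of both, 7581 between the hairpins, 1354 in the same direction and 1028 in opposite directions; array residuals with the same number correlated at 0.0571 to 0.29, and each correlated best with its own number in the other lines. The block changed the calls of the TGF-beta list with shco2 (0.034) and between the hairpins (0.0445) and of the interferon list in the mean of both (0.0489), and of no other list.

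By construction, a 2-fold minimum gave 1020, 950, 347 and 2297 calls for shco2, shco4, the mean of both and shco4 against shco2, with 120 in the same and 35 in opposite directions; an adjusted p under 0.01 gave 2294, 1887, 1185 and 4374, with 351 and 232; and 1 probe set per gene gave 4379 between the hairpins, with fewer tested. Only the 2 groups compared gave 492 in opposite directions, and both hairpins as 1 group of 6 gave 670 for the mean. With log2(value + 1), 676 were in the same and 432 in opposite directions and the correlation of fold changes was 0.243; the cause was not tested. Camera with an estimated correlation called 3, 0, 1 and 0 lists, fry, which does not compare a list with other genes, called 15 with shco4 and 23 between the hairpins, and without dim probe sets 5 were called with shco4; the cause was not tested.

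With 1 array left out, which lowers the number of samples, calls ranged from 3258 to 4602 for shco2, 2760 to 3938 for shco4, 1824 to 2938 for the mean of both, 5715 to 6691 between the hairpins, 668 to 858 in the same direction and 412 to 680 in opposite directions, the correlation from 0.125 to 0.183, and lists from 13 to 14, 7 to 10, 9 to 12 and 11 to 14. Coco's own level has no value under any setting, since no probe set is named for it. Signal over background limits what can be seen: 11.8% of probe sets were at the floor on all arrays.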

Other observations

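The gene families here were read off the symbols and the tests on them chosen only after the result was seen.

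Of 40 clustered histone genes, which encode the histones of the nucleosome and linker histone H1, 15 rose, 0 fell and 25 did not pass with shco4 against scramble, and no test of the family as a set was run (median 0.45; 0.42 with quantile normalization and 0.47 with median centring), while 0 rose and 1, H2BC21, fell with shco2. H4C8 rose with shco4 by 2.87 ± 0.15, H1-2 by 2.83 ± 0.15, H2BC21 by 2.53 ± 0.16 and H2AC6 by 2.48 ± 0.33 on the log2 scale (SE, n = 3). H4C8, H2BC21, H2AC6 and others of the 15 were read at probe sets whose identifiers mark shared sequence. The 15 may thus not be separate signals. Most of the 25 that did not pass lay at or near the floor. Between the hairpins, 15 were higher and 0 lower with shco4.

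The MHC class II pathway serves the presentation of peptides to helper T cells. Of 14 genes of this pathway, 7 were higher and 1, HLA-DOB (-1.29), lower with shco4 than with shco2, and 6 did not pass. No test of the family as a set was run, and the median was 1.07 (1.03 with quantile normalization and 1.07 with median centring). CD74, the invariant chain, fell by 0.90 with shco2 and rose by 1.17 with shco4, each ± 0.11 (SE, n = 3). HLA-DRB1 was higher with shco4 than with shco2 by 2.75, HLA-DPA1 by 2.09, HLA-DPB1 by 1.89 and HLA-DMA by 1.79. Against scramble, 0 rose and 4 fell with shco2 (median -0.29), and 4 rose and 1 fell with shco4 (median 0.67).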
